A study of Homo sapiens with 42 samples.

How the data were processed

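Per the labels' protocols, K562-FUCCI cells were fixed with formaldehyde, sorted by DNA content, digested with DpnII and ligated in situ. The DNA was then sonicated, and fragments next to each viewpoint were extended from a biotinylated primer, ligated to an adapter with random molecular barcodes and sequenced. The submitters' processing notes name cutadapt, bedtools and the genome build hg19; versions, the aligner and the treatment of the barcodes are not given in the sources used here. Per the file headers, the deposited files list 1 genomic position per line with no value column, so no other unit such as a read count, ratio or score was given by the authors. Every library held 16350 lines, so the authors' files were brought to 1 size by a step that the sources do not describe. Between 36.2% and 72.0% of a library's lines repeated a position already listed.

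The design written before the data were examined had assumed count tables and a count model. The files held positions instead, and the fallback of that design was used, limma on log2 values. Counts of lines per window could have entered a count model, but edgeR was not used. Lines were counted in 10 kb windows on chromosome 9, more than 20 kb and at most 2 Mb from the viewpoint. Windows with a mean of at least 10 lines per library were kept: 183 Proximal, 250 Distal and 183 Outside windows of 394. Library size was the sum of lines in the local zone. Values were scaled to the mean library size of the primer's libraries, and log2(value + pseudocount) was used. The pseudocount was the smallest non-zero scaled value of the primer's libraries, so that changes of low windows are understated. At that mean library size it was 0.902 lines for Proximal, 1.84 for Distal and 0.942 for Outside. Models had 7 fractions per primer and 14 libraries, with eBayes and a trend of the spread on the mean. The design did not name the trend. It was kept after the simulation below, when contact profiles had been looked at but no window had been called. Calls had a Benjamini-Hochberg adjusted p below 0.05.

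The rule for named regions was part of the same design. Windows past the threshold with the same sign in replicate 1 alone and replicate 2 alone were merged when at most 1 window apart, and up to 8 regions per direction, primer and contrast were named (up to 5 for differences between primers). The log2 change of a region is that of its strongest window. The 3 viewpoints, the distance classes and the region of largest gain over 50 kb from the viewpoint were always named. Annotation of hg19 was not used here, so regions carry no gene names. Groups and replicate numbers were taken from the labels.

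Shares were percent of a library's lines outside 20 kb of the viewpoint, in 19 classes per primer bounded at 20, 100, 250, 500, 1000 and 2000 kb on both sides. Between-fraction differences used permutation tests of the F statistic, which has no direction, with 100000 resamples. Contrasts of fractions used two-sided exact permutation tests. All were adjusted over 57 classes or 6 pairs of viewpoints. The smallest p of the resampled test is 1e-05.

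The window model was tested on simulated data drawn from the real windows' means. All windows of a primer had the same dispersion, 0.025 for Proximal, 0.00615 for Distal and 0.0163 for Outside. Simulated spread then depends on the mean alone, as the trend assumes, so the simulation cannot show that the trend suits the real windows. With all S fractions against G1 the window model recovered 85.2% of Distal windows changed 2-fold and 39.2% of those changed 1.5-fold over 250 windows. For Proximal the shares were 65.2% and 21.8%, and for Outside 79.2% and 41.8%, over 183 windows each. False calls were 7.43% of calls for Distal, 8.42% for Proximal and 6.56% for Outside, above the nominal 5%. Without the trend, false calls were 6.2% of calls for Distal and recovery of 1.5-fold changes was 27.5%. The quasi-Poisson model had fewer false calls than the trend for every primer, 4.47% of calls for Distal, 6.3% for Proximal and 5.77% for Outside. It recovered 81.8% of 2-fold changes for Distal, 47.8% for Proximal and 76.8% for Outside.

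Alternatives covered library size, windows of 5, 20 and 50 kb, the low-count filter, the excluded zone, the pseudocount, a replicate block, a quasi-Poisson model, the trend, repeated positions and leaving out libraries. Tools were R 4.3.3 with limma 3.58.1 and the data.table package (version 1.17.8), and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.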

Results

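Chromatin contacts of a fountain-like structure on chromosome 9 were measured in K562-FUCCI cells, a chronic myeloid leukaemia line that carries a fluorescent cell-cycle reporter. Cells stained with a Hoechst dye were sorted into G1 and 6 successive S-phase fractions, S1 to S6. Ligation products of a DpnII digest were read from 3 primers by biotinylated primer extension. The labels place the Proximal and Distal primers inside the structure and the Outside primer beyond it. Each combination of primer and fraction had 2 libraries, giving 21 groups and 42 libraries. Nothing in the labels says whether the 2 libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

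Each library held 16350 contact positions, a number equal in all 42, so the sequencing depth before this equalisation is unknown. The position with the most contacts in each primer's libraries was taken as its viewpoint. In hg19 coordinates these were chromosome 9 position 111624875 for Proximal, 111525048 for Distal and 111110106 for Outside. The Proximal and Distal viewpoints lay 99.8 kb apart, and Outside lay 414.9 kb from Distal. Chromosome 9 held between 86.6% and 92.5% of a library's contacts. Between 6149 and 10957 contacts per library fell in the local zone, from 20 kb to 2 Mb from the viewpoint. Counted line by line, the 2 libraries of a group had a chi-square per degree of freedom from 1.28 to 3.08 over the 21 groups, which treats repeated positions as separate molecules.

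The first comparison asked how the share of contacts at each distance differed across the cell cycle. Contacts of the Proximal primer 250 to 500 kb away on the higher-coordinate side rose from 7.34% ± 0.062 (SD, n = 2) of contacts in G1 to 16.2% ± 0.35 (SD, n = 2) in S3, and stood at 11.7% ± 0.15 (SD, n = 2) in S6. The same class of the Distal primer rose from 1.95% ± 0.036 (SD, n = 2) in G1 to 4.92% ± 0.17 (SD, n = 2) in S4. At 500 kb to 1 Mb on the higher side, the Distal share rose from 5.70% ± 0.24 (SD, n = 2) in G1 to 11.5% ± 0.53 (SD, n = 2) in S4 and was 11.4% ± 0.49 (SD, n = 2) in S6. The Outside share of that class was 1.83% ± 0.20 (SD, n = 2) in G1 and 3.84% ± 0.054 (SD, n = 2) in S4. Contacts on chromosome 9 beyond 2 Mb fell from 26.0% ± 0.35 to 12.4% ± 0.57 for Proximal, from 24.8% ± 0.73 to 11.1% ± 0.50 for Distal and from 21.8% ± 0.88 to 11.6% ± 0.56 for Outside between G1 and S4 (SD, n = 2 each).

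**Figure D1:**
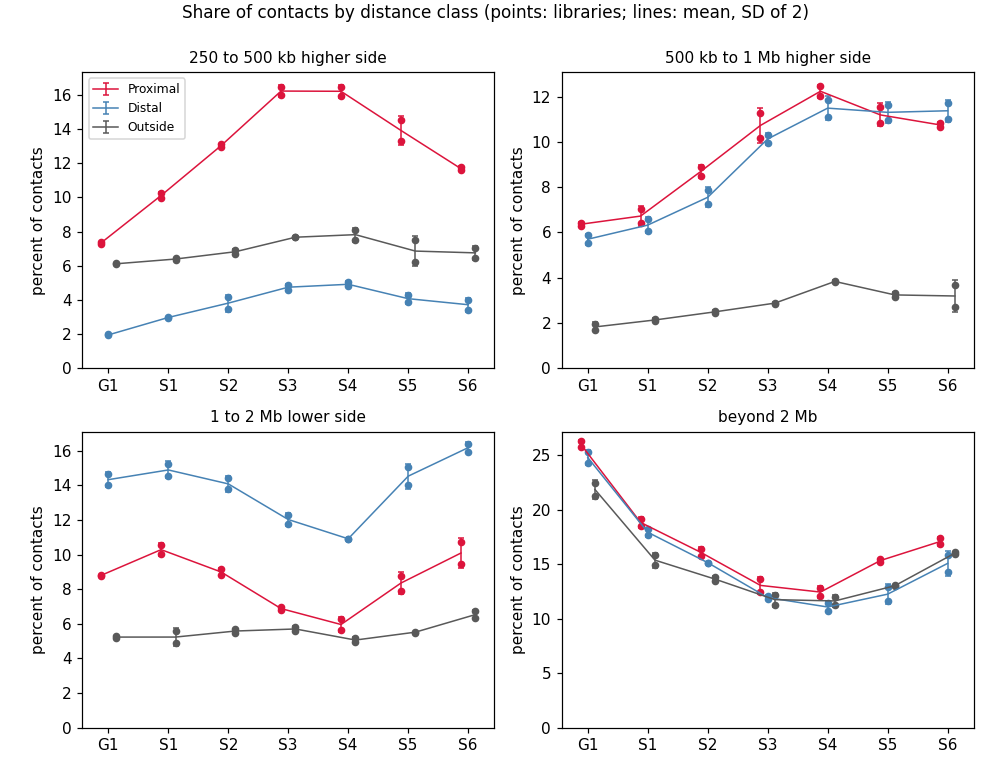
Percent of contacts (vertical axes) in 4 distance classes for G1 and S1 to S6 (horizontal axes), with a point per library and lines through the means with SD of 2 libraries, coloured by primer. The Proximal share at 250 to 500 kb on the higher side goes from 7.34% in G1 to 16.2% in S3, while contacts beyond 2 Mb fall to their lowest in S4 for each primer.

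Contacts in the class from 1 to 2 Mb on the lower side followed another course. The Proximal share was 8.80% ± 0.029 in G1, 5.96% ± 0.43 in S4 and 10.1% ± 0.86 in S6 (SD, n = 2 each). The Distal share was 14.3% ± 0.42 in G1, 10.9% ± 0.014 in S4 and 16.2% ± 0.34 in S6 (SD, n = 2 each). Both changes passed a permutation test over the 7 fractions, with adjusted p of 0.0013 for Proximal and 0.00114 for Distal. Contacts with other chromosomes made up 15.3% ± 0.12 of the Proximal total in G1 and 11.1% ± 0.51 in S4 (SD, n = 2 each).

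Permutation tests of F over the 7 fractions, with 100000 resamples, found differences in 15 of 19 Proximal, 17 of 19 Distal and 17 of 19 Outside classes after Benjamini-Hochberg adjustment over 57 measures. For the Proximal class at 250 to 500 kb on the higher side the adjusted p of that permutation test was 0.000342. Exact two-sided permutation tests of all S libraries against G1 passed in 12 Proximal classes (8 higher, 4 lower), 10 Distal classes (7 higher, 3 lower) and 7 Outside classes (4 higher, 3 lower). The smallest p this exact test can give is 0.011. Beyond 2 Mb, all 12 S libraries of each primer were below both G1 libraries, with an exact adjusted p of 0.0232. S1 to S3 differed from S4 to S6 in 2 Proximal, 2 Distal and 1 Outside class in the exact permutation test, all lower in S1 to S3. With permutation within replicate number all 5 of these calls ended. That test allows fewer splits, so its smallest p is above the 0.00216 of the unrestricted test, and it leaves the differences themselves unchanged. The lost calls therefore do not show that these differences went away. The Distal count was 0 without any 1 of the S4 and S5 libraries or S6 replicate 2, and 1 without S6 replicate 1. The Outside count was 0 without any 1 of the S1, S2 and S3 libraries or S6 replicate 1, and 2 without S4 replicate 2 or S6 replicate 2. The Proximal count was 4 without S3 replicate 2. With contacts within 2 Mb as the denominator, no class passed against G1 in any primer. The difference from G1 of the class at 250 to 500 kb on the higher side was then 6.09 points for Proximal (6.19 with the whole library) and 2.17 for Distal (2.09). For these 2 classes the lost calls do not show that the gain went away. The smaller denominator raises the G1 share too, so equal points are a smaller fold. From 111890001 to 112270000, the fold of S over G1 was 1.79 with the whole library and 1.44 within 2 Mb for Proximal. It was 1.94 and 1.58 for Distal, and 1.79 and 1.53 for Outside. Of the 19 classes called higher over all primers, 6 kept a difference in points within 1.5 times, 12 shrank by more and 1 reversed. The Proximal class at 100 to 250 kb went from 2.53 to 0.624 points, that at 500 kb to 1 Mb from 3.65 to 1.58, and the Outside class at 250 to 500 kb from 2.59 to 0.747. With this denominator the adjusted p for the Proximal class at 250 to 500 kb on the higher side was 0.148 in the exact test, the highest of a range from 0.0211 over the settings tried. Without either G1 library no class could pass, since 1 library remained.

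In the permutation test over the 7 fractions, 7 classes lost their call with 1 library left out. For Proximal these were 1 to 2 Mb higher (adjusted p 0.0685 without S3 replicate 2), 100 to 250 kb higher (0.073 without G1 replicate 2) and 20 to 100 kb lower (0.0728 without S5 replicate 1). For Distal they were 1 to 2 Mb higher (0.0567 without S6 replicate 1), 250 to 500 kb lower (0.0748 without G1 replicate 2) and other chromosomes (0.0781 without G1 replicate 2). For Outside it was 250 to 500 kb higher (0.0996 without S4 replicate 2).

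The second comparison asked which 10 kb windows of the local zone changed from G1 to S phase, relative to all contacts of that zone. For the Proximal primer, 3 regions were higher in S. The region at 111950001 to 112020000 rose most firmly: its strongest window held 30.9 ± 1.5 contacts per 10000 local contacts in G1 and 97.4 ± 8.2 in S4 (SD, n = 2 each), and 80.4 ± 6.1 in S6. Its log2 change over all S fractions was 1.36 (limma, adjusted p = 8.04e-05). The window starting at 111890001, 270.1 kb from the viewpoint, had the largest log2 change among the Proximal windows past the threshold, 1.48 (limma, adjusted p = 0.0108). The window at 112170001 to 112180000 had a log2 change of 0.87 (limma, adjusted p = 0.0457). Both single windows lost their call when a G1 library was left out: without G1 replicate 2 the first had an adjusted p of 0.309, and without G1 replicate 1 the second had 0.639.

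From the Distal primer, 16 windows rose and 3 fell. The largest gain lay at 111940001 to 111980000, where the strongest window held 10.4 ± 2.7 contacts per 10000 in G1 and 45.7 ± 2.4 in S3 (SD, n = 2 each), a log2 change over all S fractions of 1.56 (limma, adjusted p = 1.3e-08). The adjoining region at 112000001 to 112020000 rose by 1.36 on the log2 scale (limma, adjusted p = 1.1e-07). Farther out, the window at 112260001 to 112270000 held 9.2 ± 0.92 contacts per 10000 in G1 and 43.4 ± 1.9 in S6 (SD, n = 2 each), with a log2 change of 1.25 (limma, adjusted p = 1e-04). The regions at 112150001 to 112180000, 112040001 to 112050000 and 112090001 to 112110000 had log2 changes of 1.08, 0.95 and 0.77. Nearer to the viewpoint, 111730001 to 111740000 had a log2 change of 1.08, and 111250001 to 111260000, on the lower side, of 0.51.

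The 3 Distal windows that fell lay on the lower side, 109960001 to 109970000 with a log2 change of -0.87, 110240001 to 110250000 with -0.76 and 110180001 to 110190000 with -0.49 (limma, adjusted p of 0.029, 0.0202 and 0.0481). The last of them held 98.6 ± 19.3 contacts per 10000 in G1, 50.1 ± 8.6 in S3 and 89.2 ± 5.1 in S6 (SD, n = 2 each). These falls are relative to the local zone. With scaling to the whole library the adjusted p of the 3 windows was 0.126, 0.135 and 0.433 (ranges over all settings 0.00448 to 0.243, 0.00431 to 0.303 and 0.00344 to 0.537), and the Distal primer had 62 windows higher and 0 lower.

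The Outside primer had 1 window past the threshold, 112160001 to 112170000, 1055.0 kb from the viewpoint. Both G1 libraries together held 1 contact there, against 6 to 20 in each of the 12 S libraries. The ratio of the pooled shares was 23.1, with a 95% counting interval (Clopper-Pearson) from 4.08 to 917 that covers counting error only. Its adjusted p was 3.18e-05 in limma and 0.805 in a quasi-Poisson model added after the data were examined, with a range from 5.7e-06 to 0.805 over all settings.

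**Figure D2:**
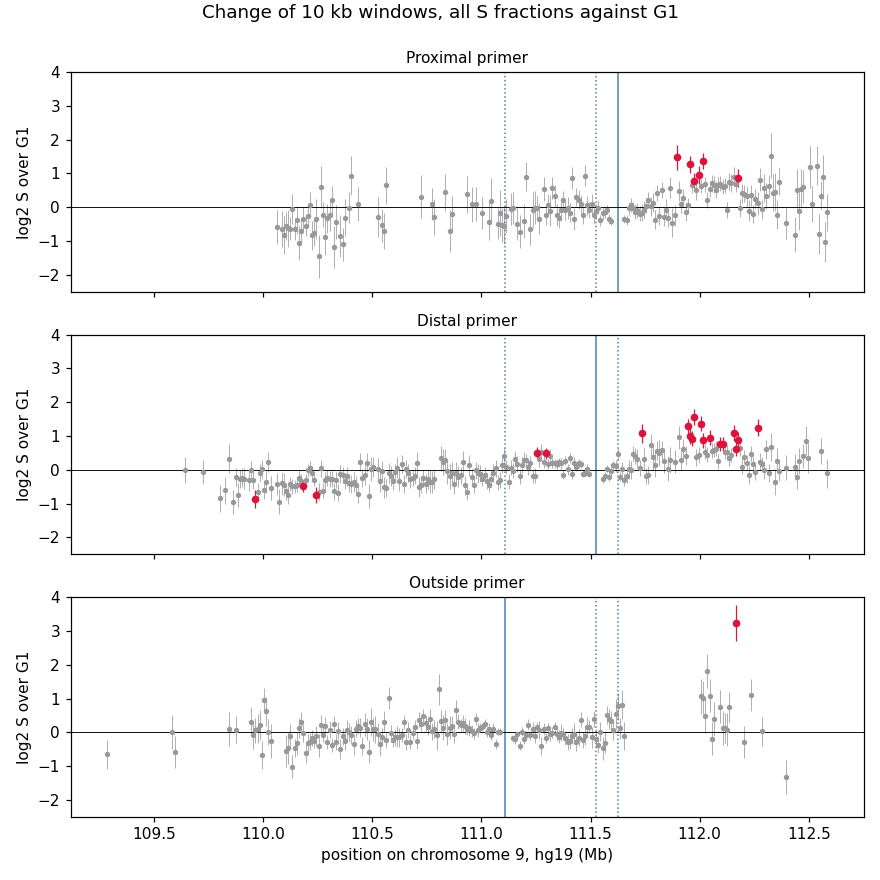
Log2 change of 10 kb windows from G1 to all S fractions (vertical axes, bars give the standard error) along chromosome 9 in Mb of hg19 (horizontal axis), 1 panel per primer, with solid blue lines at the panel's own viewpoint and dotted lines at the others. Red windows passed the threshold, 6 for Proximal, 19 for Distal and 1 for Outside, and most lie above the Proximal viewpoint.

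In limma on log2 values with Benjamini-Hochberg adjustment, all S fractions against G1 gave 6 of 183 Proximal windows (6 higher), 19 of 250 Distal windows and 1 of 183 Outside windows (1 higher). Unadjusted p below 0.05 was found in 36 Proximal, 61 Distal and 17 Outside windows. The Proximal count was 18 without S1 replicate 1, 17 without S5 replicate 2, 12 without S6 replicate 1, 10 without S6 replicate 2 and 3 without either S4 library. The Distal count was 12 without G1 replicate 1 and 10 without G1 replicate 2. The Outside count was 5 without G1 replicate 2, 3 without S2 replicate 2, 3 without S6 replicate 2 and 2 without S1 replicate 2.

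Leaving out 1 G1 library also ended the Distal calls at 111730001, 112040001, 112090001, 109960001 (without G1 replicate 2, adjusted p 0.301, 0.356, 0.436 and 0.243), and at 112150001, 111250001, 110240001 and 110180001 (without G1 replicate 1, adjusted p 0.0704, 0.671, 0.303 and 0.537). The Proximal region at 111950001 to 112020000 and the Distal regions at 111940001 to 111980000 and 112000001 to 112020000 stayed past the threshold with every library left out in turn and under each of the other settings tried.

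**Figure D3:**
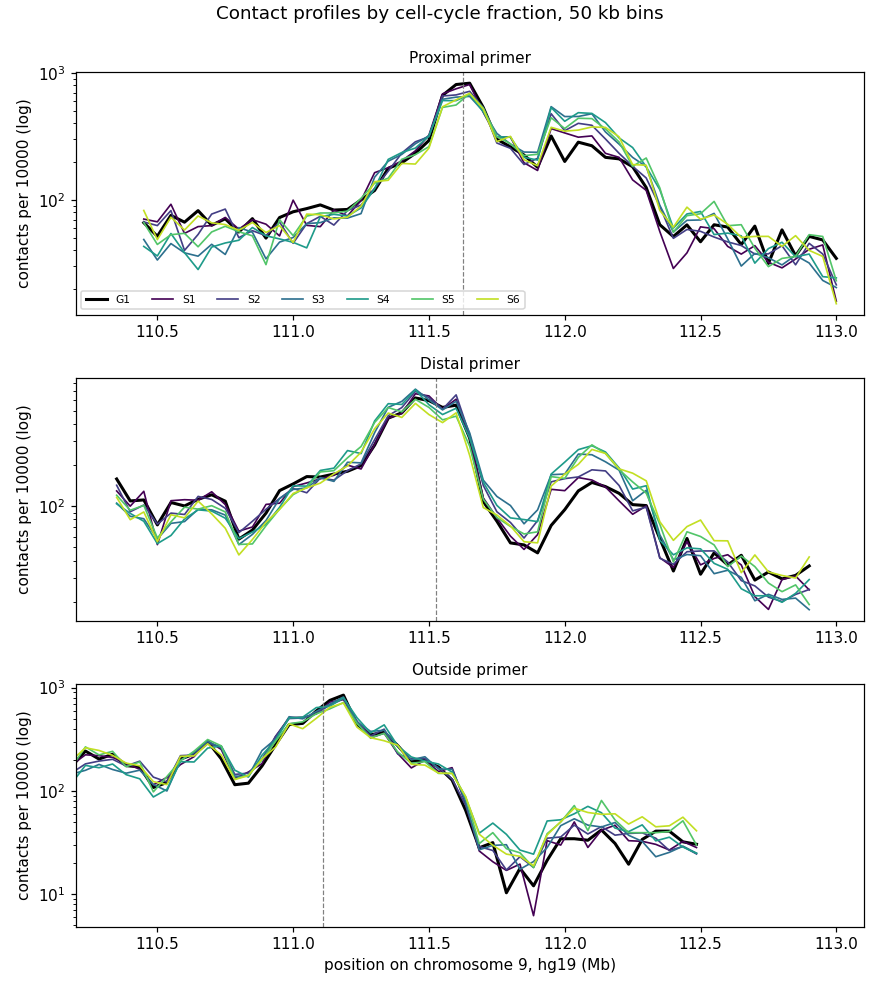
Mean contacts per 10000 local contacts in 50 kb bins (log axes) along chromosome 9 in Mb of hg19, for G1 in black and S1 to S6 in colours from dark to light, 1 panel per primer, with contacts within 20 kb of the viewpoint (dashed line) left out. Around 112 Mb the curves of S3 to S5 lie above G1 for Proximal and Distal, while the low curves of Outside overlap more.

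Each S fraction was also set against G1. From the Proximal primer no window passed in S1 (limma; 22 had an unadjusted p below 0.05, the quasi-Poisson model and limma without the trend also gave 0, while whole-library scaling gave 2, and windows of 5, 20 and 50 kb gave 3, 1 and 2), 3 did in S2, 13 in S3, 23 in S4, 12 in S5 and 1 in S6. From the Distal primer 3 windows passed in S1, 4 in S2, 20 in S3, 55 in S4, 19 in S5 and 16 in S6. The Outside counts were 1, 1, 2, 1, 1 and 3. In S4, 14 Proximal windows were higher and 9 lower, and 30 Distal windows were higher and 25 lower. The 25 lower Distal windows of S4 lay between 109860001 and 110650000. In S6 the 13 higher Distal windows lay between 111940001 and 112270000. The 6 contrasts of a primer share the same G1 libraries.

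Every one of these counts moved by over 1.5 times with at least 1 library left out. For Proximal, S1 gave 2 windows without G1 replicate 2 and 7 without S1 replicate 2. S2 gave 0 without either S2 library and 1 without G1 replicate 2 or either S4 library. S3 gave 3 without S3 replicate 1, 5 without G1 replicate 2, 6 without S2 or S3 replicate 2 and 8 without S2 replicate 1. S4 gave 2 without S4 replicate 1, 8 without S4 replicate 2, 6 and 11 without G1 replicate 1 and 2, and 14 without S2 replicate 2. S5 gave 1 without either S5 library, 5 without either S4 library, and 7 and 4 without G1 replicate 1 and 2. S6 gave 0 without either S6 library and 2 without either G1 library.

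For Distal, S1 gave 1 window without G1 replicate 1, 0 and 6 without S1 replicate 1 and 2, and 5 without either S6 library. S2 gave 1 and 2 without G1 replicate 1 and 2, and 0 without S2 replicate 1. S3 gave 6 and 8 without S3 replicate 1 and 2, and 9 without G1 replicate 2. S4 gave 33 and 31 without S4 replicate 1 and 2, and 24 without G1 replicate 2. S5 gave 12 without either G1 library and 9 without S5 replicate 1, and S6 gave 10 without S6 replicate 1 and 9 without G1 replicate 2. For Outside without G1 replicate 2, S1 to S5 gave 0, 2, 4, 4 and 4, and without G1 replicate 1, S3 and S6 gave 1 each. Outside counts fell to 0 in S1 without S1 replicate 1, in S2 without either S2 library or S3 replicate 1, in S3 without S3 replicate 1, in S5 without S3 or S5 replicate 1 and in S6 without S6 replicate 1, while S1 gave 2 without S1 replicate 2.

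The omnibus test over the 7 fractions called 14 Proximal, 58 Distal and 1 Outside window (limma). The Proximal count was 22 without S1 replicate 2 and 3 without S4 replicate 1. It was also 4 without G1 replicate 1, 5 without G1 replicate 2, 6 without S2 replicate 1, 4 without S2 replicate 2, 8 without S3 replicate 1, 7 without S4 replicate 2 and 8 without S5 replicate 1. The Outside window was lost without G1 replicate 1 and without S3 replicate 1, which left a count of 0.

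The third comparison set the early fractions S1 to S3 against the late fractions S4 to S6. From the Distal primer, windows near the viewpoint were higher early and windows far on the higher side were higher late. The early group included 111450001 to 111500000, whose strongest window held 154.4 ± 34.7 contacts per 10000 in S3 and 98.9 ± 5.3 in S6 (SD, n = 2 each), and 111570001 to 111600000, with a log2 change of 0.40 (early over late; limma, adjusted p = 0.00131). The region at 111620001 to 111640000, which contains the Proximal viewpoint, had a log2 change of 0.41. The late group included 112070001 to 112200000, with 20.6 ± 8.8 contacts per 10000 in S1 and 55.4 ± 7.8 in S6 (SD, n = 2 each) and a log2 change of -0.71 (limma, adjusted p = 0.00131). Farther out, 112220001 to 112290000 had a log2 change of -0.71 and 112440001 to 112450000 of -1.05.

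On the lower side of the Distal viewpoint, 110710001 to 110740000 had a log2 change of 0.65, 110860001 to 110870000 of 0.70 and 110950001 to 110960000 of 0.55, all higher early. Between the Distal and Outside viewpoints, 111240001 to 111250000, 111280001 to 111300000 and 111320001 to 111330000 were higher late, with log2 changes of -0.67, -0.43 and -0.52. Limma called 35 Distal windows, 13 higher and 22 lower in S1 to S3. The Distal count was 23 without S2 replicate 1, 21 without S2 replicate 2, 21 without S5 replicate 1, and 0 in limma without a trend of the spread on the mean. No Proximal and no Outside window passed in limma, 25 and 14 had an unadjusted p below 0.05, and a quasi-Poisson model called 0 in both, while 50 kb windows gave 9 for Proximal and 7 for Outside. The Proximal count was 1 without S2 replicate 1 and 4 without S1 replicate 2.

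Some Distal regions of this comparison lost their call with 1 library left out. Without S6 replicate 2 the adjusted p was 0.22 at 110860001, 0.168 at 110950001 and 0.188 at 111620001, and without S4 replicate 1 it was 0.0572 at 111280001.

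The fourth comparison tested whether the change from G1 to S differed between primers, in windows measured from both. The change at 112160001 to 112170000 was smaller from Proximal than from Outside, with a difference of -2.55 in log2 change (limma, adjusted p = 0.0197), and smaller from Distal than from Outside, with -2.61 (limma, adjusted p = 0.000142). Both rest on the single G1 contact of the Outside libraries. At 111940001 to 111950000 the log2 change was 0.07 from Proximal and 1.32 from Distal in the joint model of both primers, and the difference was -1.25 (limma, adjusted p = 0.0294). Each comparison had 1 window past the threshold, out of 108 for Proximal and Outside, 172 for Distal and Outside and 167 for Proximal and Distal.

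Leaving out 1 library ended the Proximal and Outside call (0 windows without Proximal G1 replicate 1, Outside S3 replicate 1 or Outside G1 replicate 2) and the Proximal and Distal call (0 windows without any 1 of the 4 G1 libraries or Proximal S4 replicate 2). The Distal and Outside count was 2 without Outside S2 replicate 1 or Outside S5 replicate 2, and 3 without Outside G1 replicate 2 or Outside S1 replicate 2. Across shared windows the changes of Proximal and Distal correlated with r of 0.523, those of Proximal and Outside with 0.377 and those of Distal and Outside with 0.355. Windows are not independent replicates. The primers share no libraries, but whether they share sorted cells or ligated DNA was not established here.

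The last comparison asked how often each viewpoint met the neighbourhood, within 25 kb, of the others. The Distal primer met the Proximal site with 2.35% ± 0.23 (SD, n = 2) of its contacts in G1, 3.43% ± 0.24 (SD, n = 2) in S2 and 2.55% ± 0.086 (SD, n = 2) in S6. The Outside primer met the Proximal site with 0.448% ± 0.024 (SD, n = 2) in G1 and 0.730% ± 0.022 (SD, n = 2) in S5, and all 12 S libraries lay above both G1 libraries. The Proximal primer met the Distal site with 2.73% ± 0.087 (SD, n = 2) in G1 and 3.20% ± 0.13 (SD, n = 2) in S1, which did not pass.

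The permutation test over the 7 fractions passed for 2 of 6 pairs, Distal to Proximal (adjusted p = 0.0115) and Outside to Proximal (adjusted p = 0.012). No pair passed in the exact test of S against G1, where both had an adjusted p of 0.0659 and where 2 passed without Distal S6 replicate 1. Outside to Proximal already had the smallest p this exact test can give, 0.011. After adjustment over 6 pairs it could not pass unless another pair also reached that p. Its failure therefore does not argue against a difference. Distal to Proximal was higher in S1 to S3 than in S4 to S6 (exact permutation test, adjusted p = 0.039), a call that ended, with a count of 0, without any 1 of 10 of the 12 Distal S libraries, under a 50 kb neighbourhood, with a 50 kb excluded zone and with permutation within replicate number. Early against late, 2 pairs passed without Outside S3 replicate 1 and 3 without Proximal S4 replicate 2.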

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

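The 3 differences between primers come from planned tests, and the counts in windows on other chromosomes were chosen only after the data were examined.

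The change from G1 to S differed between primers in 3 tests on 10 kb windows of chromosome 9. At 112160001 to 112170000 it was smaller from Proximal than from Outside by a log2 difference of -2.55 and smaller from Distal than from Outside by -2.61, and the 2 Outside G1 libraries held 1 and 0 contacts there. At 111940001 to 111950000 the change was smaller from Proximal than from Distal, with a log2 difference of -1.25. This window was the strongest Proximal contact over 100 kb away in G1, with 110.9 ± 2.4 contacts per 10000 (SD, n = 2).

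Contacts with other chromosomes entered the comparisons only as a total. The fullest 10 kb window there held 266 Proximal contacts, on chromosome 2 at 101180001 to 101190000, at 2 positions and in all 14 libraries, against 8 Distal and 0 Outside contacts. For Distal it held 68 contacts, on chromosome 2 at 223500001 to 223510000, at 1 position in 14 libraries, against 0 for both other primers. For Outside it held 40 contacts, on chromosome 1 at 121480001 to 121490000, where Proximal had 39 and Distal 23. No explanation for these windows was tested.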

How the results depend on the processing

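The quasi-Poisson model, limma without the trend, positions counted once, 50 kb windows and the removal of both S1 libraries were chosen after the data were examined. The planned edgeR test was not run, although the counts of lines per window could have been used for it. Of 392 values of named regions under other settings, 297 kept direction and side of the threshold and 95 kept direction but lost the call. Of 180 values of shares, 157 kept both, 19 lost and 3 gained the call. The Proximal share at 250 to 500 kb on the lower side reversed, with a difference from G1 of -0.073 with contacts within 2 Mb as denominator. Scaling to the whole library shifted the log2 change of S over G1 by 0.30 for Proximal, 0.29 for Distal and 0.22 for Outside. The highest adjusted p over all settings was 0.0417 for the Proximal region at 111950001 to 112020000, and 0.0126 and 0.0281 for the Distal regions at 111940001 to 111980000 and 112000001 to 112020000. Of 30 named regions, 16 lost their call with 1 library left out and 19 without the trend. Except where stated, the cause of a change was not tested.

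Counts of windows below are in the order any fraction, all S, S1 to S3 against S4 to S6, then S1 to S6 each against G1. Counts between primers are in the order Proximal minus Outside, Distal minus Outside, Proximal minus Distal. Proximal counts with whole-library scaling were 35, 27, 0, 2, 14, 29, 33, 22 and 10. Distal counts with whole-library scaling were 93, 62, 33, 7, 22, 61, 75, 49 and 36. Outside counts with whole-library scaling were 2, 7, 0, 1, 1, 7, 12, 3 and 2. Between primers there were 0, 1 and 1. Proximal counts with TMM scaling were 9, 4, 0, 0, 1, 13, 21, 6 and 1. Distal counts with TMM scaling were 60, 19, 34, 2, 4, 20, 53, 15 and 13. Outside counts with TMM scaling were 1, 1, 0, 1, 1, 2, 1, 1 and 4. The counts between primers were 0, 1 and 1. Proximal counts with 20 kb windows were 24, 11, 0, 1, 3, 15, 26, 8 and 2. Distal counts with 20 kb windows were 50, 21, 29, 3, 4, 29, 48, 16 and 20. Outside counts with 20 kb windows were 9, 5, 0, 1, 0, 8, 1, 0 and 5. Differences between primers numbered 3, 2 and 0. Proximal counts with 5 kb windows were 1, 10, 0, 3, 3, 5, 9, 8 and 1. Distal counts with 5 kb windows were 44, 32, 20, 1, 1, 21, 54, 26 and 18. Outside counts with 5 kb windows were 0, 0, 0, 0, 0, 0, 0, 0 and 2. Primer comparisons then gave 0, 0 and 0. Proximal counts with 50 kb windows were 26, 9, 9, 2, 3, 17, 20, 7 and 8. Distal counts with 50 kb windows were 48, 28, 23, 3, 11, 33, 42, 14 and 16. Outside counts with 50 kb windows were 18, 7, 7, 0, 0, 7, 10, 4 and 6. For primer pairs the counts were 4, 5 and 2. Proximal counts with no low-count filter were 20, 7, 0, 0, 2, 12, 19, 7 and 1. Distal counts with no low-count filter were 55, 21, 30, 2, 4, 23, 61, 20 and 15. Outside counts with no low-count filter were 1, 1, 0, 1, 1, 2, 2, 1 and 4. Pairs of primers gave 1, 5 and 1. Proximal counts with a 50 kb excluded zone were 8, 4, 0, 0, 1, 8, 20, 5 and 1. Distal counts with a 50 kb excluded zone were 62, 21, 26, 3, 4, 24, 54, 20 and 12. Outside counts with a 50 kb excluded zone were 1, 1, 0, 1, 1, 2, 1, 1 and 3. Pairwise counts were 1, 1 and 1. Proximal counts with a replicate block were 16, 10, 0, 0, 4, 19, 24, 16 and 1. Distal counts with a replicate block were 58, 19, 36, 3, 4, 25, 54, 21 and 16. Outside counts with a replicate block were 1, 1, 0, 1, 1, 2, 1, 1 and 3. The pairs of primers had 1, 1 and 1. Proximal counts with a pseudocount 10 times larger were 17, 17, 0, 0, 1, 14, 23, 12 and 1. Distal counts with a pseudocount 10 times larger were 60, 24, 33, 2, 4, 22, 54, 21 and 16. Outside counts with a pseudocount 10 times larger were 0, 1, 0, 0, 0, 1, 0, 0 and 4. Pair counts came to 0, 0 and 0. Proximal counts with a quasi-Poisson model were 14, 2, 0, 0, 0, 2, 10, 0 and 0. Distal counts with a quasi-Poisson model were 59, 13, 37, 0, 2, 10, 46, 13 and 7. Outside counts with a quasi-Poisson model were 0, 0, 0, 0, 0, 0, 0, 0 and 0. Primer pairs gave 0, 0 and 0. Proximal counts with limma without a mean trend were 1, 1, 0, 0, 0, 0, 4, 2 and 1. Distal counts with limma without a mean trend were 7, 14, 0, 0, 4, 11, 32, 9 and 4. Outside counts with limma without a mean trend were 0, 1, 0, 0, 0, 3, 1, 0 and 2. Counts between pairs were 1, 2 and 0. Proximal counts with positions counted once were 2, 2, 0, 0, 0, 5, 13, 2 and 1. Distal counts with positions counted once were 58, 28, 29, 4, 4, 31, 48, 26 and 19. Outside counts with positions counted once were 3, 1, 0, 0, 0, 2, 0, 0 and 1. Primer pairs had 0, 0 and 0. With both S1 libraries left out, all S against G1 gave 20 Proximal, 34 Distal and 2 Outside windows.

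Splits into higher and lower calls moved with the scaling. With whole-library scaling the Distal calls of all S were 62 higher and 0 lower (16 and 3 with local scaling), and those of S1 to S3 against S4 to S6 were 4 and 29 (13 and 22). Proximal S4 and S5 gave 30 and 3 (14 and 9), and 21 and 1 (10 and 2). Distal S3, S4, S5 and S6 gave 57 and 4 (13 and 7), 67 and 8 (30 and 25), 49 and 0 (17 and 2), and 36 and 0 (13 and 3). Outside S3 and S6 gave 6 and 1 (1 and 1), and 2 and 0 (2 and 1). With TMM scaling, Proximal all S, S3, S4 and S5 gave 3 and 1 (6 and 0), 8 and 5 (12 and 1), 10 and 11 (14 and 9), and 4 and 2 (10 and 2), and Outside S6 gave 2 and 2 (2 and 1).

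Proximal counts ranged over 3 to 22, 3 to 18, 0 to 4, 0 to 7, 0 to 4, 3 to 17, 2 to 25, 1 to 13 and 0 to 2 with 1 library left out at a time. Distal counts ranged over 48 to 70, 10 to 27, 21 to 34, 0 to 6, 0 to 4, 6 to 30, 24 to 58, 9 to 23 and 9 to 17 with 1 library left out at a time. Outside counts ranged over 0 to 1, 1 to 5, 0 to 0, 0 to 2, 0 to 2, 0 to 4, 1 to 4, 0 to 4 and 0 to 4 with 1 library left out at a time. Between primers the ranges were 0 to 1, 1 to 3 and 0 to 1. Proximal distance classes ranged over 13 to 15, 0 to 12 and 2 to 4 past the threshold. Distal distance classes ranged over 15 to 18, 0 to 12 and 0 to 3 past the threshold. Outside distance classes ranged over 16 to 17, 0 to 9 and 0 to 2 past the threshold. Primer-site contacts ranged over 2 to 3, 0 to 2 and 0 to 3.

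Classes past the threshold are in the order any fraction, all S against G1, S1 to S3 against S4 to S6. With a 50 kb excluded zone they were 14, 12 and 2 for Proximal, 15, 9 and 3 for Distal and 16, 8 and 3 for Outside, and 2, 0 and 0 for pairs of viewpoints. With contacts within 2 Mb as denominator, and 15 classes per primer, they were 9, 0 and 4, then 14, 0 and 5, then 10, 0 and 1, and 3, 0 and 3 for pairs of viewpoints. A 50 kb neighbourhood gave 3, 0 and 0 pairs, and 10 kb gave 2, 0 and 1. With permutation within replicate number (replicate block) they were 16, 12 and 0, then 17, 11 and 0, then 18, 7 and 0, and 2, 0 and 0 for pairs. With 1 G1 library left out the exact test cannot pass, which gives the 0 of all S against G1.

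Log2 values of windows deviated together in same-numbered libraries with a median correlation of 0.025 for Proximal, -0.023 for Distal and 0.038 for Outside. These medians are over 21 pairs of fractions and do not measure library-wide offsets. The share at 20 to 100 kb was higher in replicate 2 in every fraction for Proximal and for Outside. In G1 it was 15.6% and 17.7% for Proximal replicates 1 and 2, and 16.3% and 17.2% for Outside. For Distal the order varied, with 14.5% and 13.8% in G1 and 15.9% and 17.5% in S1. The replicate block moved the Proximal count of all S against G1 from 6 to 10.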

Other observations

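All tests here were chosen only after the results were seen, apart from the main limma window tests. Those are cited in the next paragraph, for differences between primers at single windows and for the real count of S1 to S3 against S4 to S6.

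Before S phase, the strongest contacts over 100 kb away lay in different windows for each viewpoint. The ranking made no correction for distance, so it does not set these windows apart from a fall of contacts with distance. In G1 the Proximal primer was strongest at 111940001 to 111950000, 320.1 kb away, with 110.9 ± 2.4 contacts per 10000 (SD, n = 2). The Distal primer was strongest at 111370001 to 111380000 with 147.0 ± 11.2, followed by 111630001 to 111640000 with 121.9 ± 15.7 (SD, n = 2 each). The Outside primer was strongest at 111220001 to 111230000 (114.9 kb) with 139.5 ± 15.5, followed by 111000001 to 111010000 (-105.1 kb) with 138.3 ± 24.0 (SD, n = 2 each). These 5 windows had log2 changes over all S fractions from -0.20 to 0.15, and none passed (limma, lowest adjusted p = 0.391). The mean over S hides calls in other contrasts at the Distal window 111630001 to 111640000. It was lower in S6 than in G1, and was part of a region called higher in S1 to S3 than in S4 to S6.

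The spread of contacts along chromosome 9 beyond 2 Mb also differed between G1 and S. From the Distal primer, the stretch from 100 to 110 Mb held 38.9% ± 0.82 (SD, n = 2) of these far contacts in G1 and 51.1% ± 1.8 (SD, n = 12) in all S libraries. From 110 to 120 Mb, which holds the locus, the Distal share went from 19.5% ± 0.20 (SD, n = 2) to 17.5% ± 0.68 (SD, n = 12), while the Proximal share went from 22.5% ± 2.0 (SD, n = 2) to 25.3% ± 2.1 (SD, n = 12). From 120 to 130 Mb the Distal share was 13.0% ± 0.062 (SD, n = 2) in G1 and 9.34% ± 1.6 (SD, n = 12) in S. On the short arm, the Distal share in G1 was 2.30% ± 0.36 from 30 to 40 Mb and 0.236% ± 0.075 from 20 to 30 Mb. It was 0.103% ± 0.059 from 10 to 20 Mb and 0.177% ± 0.035 from 0 to 10 Mb (SD, n = 2 each). No test was run on these values.

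The named Proximal and Distal regions that were higher in S and began over 250 kb above the Proximal viewpoint marked out a span of 380 kb, 111890001 to 112270000, whose share of local contacts went from 18.0% ± 0.81 to 26.0% ± 3.4 for Proximal, from 8.37% ± 0.38 to 13.2% ± 2.2 for Distal and from 2.27% ± 0.12 to 3.48% ± 0.64 for Outside (SD, n = 2 in G1 and 12 in S). Since calls in the Proximal and Distal libraries chose the span, only Outside tests it (exact permutation p = 0.022). There, 12 of 12 S libraries lay above both G1 libraries in percent of local contacts, and 12 of 12 with each position counted once, which argues against a loss of far contacts from the denominator and against repeated lines at few positions as the whole cause for Outside. More DNA copies of the span during replication may account for the gain and cannot be told apart from a change of folding. For all S against G1, the log2 change of the whole span differed by -0.075 for Proximal minus Outside. It differed by 0.043 for Distal minus Outside and -0.118 for Proximal minus Distal (permutation p 0.429, 0.567 and 0.191). S6 against S4 was also tested, with 2 libraries per group, which limits how low its permutation p can go. The lowest adjusted permutation p over both contrasts was 0.552. The folds of local contacts in S4 were 1.68, 1.85 and 1.76, under the 2 that copies allow. Values that go against copies alone are the differences between primers at single windows of the span, -1.25 at 111940001 and -2.55 and -2.61 at 112160001 (limma, adjusted p 0.0294, 0.0197 and 0.000142, with highest values over the settings of 0.965, 0.691 and 0.6), the S6 folds of 1.36, 1.70 and 1.80, S4 folds of 2.19, 2.38 and 2.14 with all contacts outside 20 kb as denominator, and single regions with folds over all S of 2.56 for Proximal and 2.95 and 2.57 for Distal; replication timing was not analysed here, the S4 folds include the loss of far contacts, the regions were chosen for their gain, and the differences at 112160001 rest on 1 Outside contact in G1.

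The mean position of the excess over G1 differed between early and late fractions from both inner primers. In the zone of 750 kb from 111874876 to 112624875, it had a Spearman's rho with the S number, over the 10 libraries of S2 to S6, of 0.96 for Proximal (permutation adjusted p = 0.00036) and 0.935 for Distal (permutation adjusted p = 0.00072), with Pearson's r of 0.945 and 0.846 (permutation adjusted p 0.00042 and 0.0006), 0.923 and 0.924 without the 2 libraries farthest from the median fraction, and rho of 0.927 and 0.976 over S3 to S6 alone (permutation p 0.0033 and 0.0008, n = 8). The excess is net of gains and losses and could not be placed in S1, which was left out (1.81 and 304.3 kb above the Proximal viewpoint for Proximal, 432.0 and -756.5 kb for Distal), nor for Outside in S2 and S3 (rho 0.935), and the plain mean position over all 12 S libraries had rho of 0.834 for Proximal (permutation adjusted p = 0.00215), 0.396 for Distal (0.251) and -0.17 for Outside (0.609), with p adjusted over these 6 relations. A gain of fixed shape that fades would keep the position of its excess, so the values argue against it alone for Proximal and Distal. The excess of every library of a primer is taken over the same G1 libraries, whose spread these permutations leave out. Outward movement is not shown, since the plain mean in S6 was back near G1 (517.9 ± 0.77 against 516.6 ± 10.0 kb for Proximal, 563.5 ± 6.1 against 569.7 ± 7.7 kb for Distal, SD, n = 2 each), so that a rise of the whole zone in its G1 shape, as more DNA copies may give, stays open.

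As a hypothesis, a structure whose contacts mirror each other across a fixed axis could place the Distal gain farther out than the Proximal gain by the 99.8 kb between their viewpoints. The mean position of the excess in S2 to S6 was 461.8 ± 78.4 kb above the Proximal viewpoint for Distal and 474.8 ± 41.8 kb for Proximal (SD, n = 10 each). Cut at the edges of the zone, the Proximal excess moved outward by that distance gives an expected shift of 97.5 kb. The Distal minus Proximal difference of -13.0 kb departed from it (exact permutation within fractions, p = 0.000257, the smallest it can give) and was not distinguishable from 0 (p = 0.577). This argues against this simple form of mirroring as the source of the whole excess. A rise of the same stretch from both primers, as more DNA copies may give, was not separated from the excess. The test therefore cannot decide whether part of the excess is mirrored.

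Other divisions of the 12 S libraries of a primer into 6 and 6 were compared with S1 to S3 against S4 to S6. For Distal, 1 of 100 splits, the real one, gave as many as 35 windows, and the highest other gave 7. The other splits part the 2 libraries of a fraction, so differences among fractions enter their residual spread and lower their counts. The gap between 35 and 7 therefore does not exclude a chance division. Of the 10 splits that keep fractions whole, too few for a share under 0.05, the highest other, S1, S2 and S6 against S3 to S5, gave 31, so the count does not set early against late apart from other differences among fractions. In limma without the trend the real count was 0. For Proximal and Outside the real count was 0, which 100 of 100 splits reach whatever the libraries hold, so the comparison decides nothing there; the highest others gave 4 and 1.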
